A study of Mus musculus with 12 samples.

How the data were processed

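RNA from basal forebrain and cortex of 6 mice was measured on 12 Agilent SurePrint G3 Mouse GE v2 arrays in 1 colour. Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09, which writes a processed intensity per spot. By those headers that intensity is background-subtracted, spatially detrended and multiplicatively detrended, holds substitute values for spots too dim to measure, and is not scaled between arrays. The deposited series table holds the same intensities: 99.998% of its raw values equalled the scanner value within 0.01 log2. The authors' normalized log2 values in the same table have identical sorted values on all 12 arrays, which is what quantile normalization over the arrays leaves. How they were made is otherwise not given in the sources used here. They served as an alternative only, and the table's 12 flag columns were not used here.

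The array holds 59305 spots of 56605 probes without controls. The log2 values of the unflagged spots of a probe were averaged, 37 probes with every spot flagged on an array were left out, and 56568 were analysed. A RefSeq table supplied the current symbol for 32972 probes, and 23596 kept the name in the files, giving 37042 gene names. Probe positions are those in the files, in the mm9 build. No genome sequence was used here. No spot was saturated (0 over all arrays).

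Log2 intensity minus the 75th percentile of its array was compared, so a level of 0 is that percentile. Each gene was read from its brightest probe on average. A gene entered a comparison when the scanner called that probe well above background on all 3 arrays of at least 1 group. R 4.3.3 was used with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table. Differences were tested with limma, lmFit and eBayes with trend=TRUE, and p was adjusted over all genes of a comparison by Benjamini-Hochberg. A gene passed with an adjusted p under 0.05. Each region was fitted on its own 6 arrays. For the genotype difference over both regions the 2 arrays of a mouse were averaged first, which leaves 6 values, 1 per mouse. The region comparisons and the interaction (the genotype difference in basal forebrain minus that in cortex) came from a single fit of all 12 arrays in 4 groups. All replicates are separate mice by the sample labels, 3 per genotype, and their number limits precision.

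Before the data were examined, 37 gene lists, the main tests, most alternatives and the rule for the genes to be named were fixed. Of the lists 36 were tested. The list of Y-linked genes and Xist was measured but not tested because fewer than 5 of its genes entered. Camera in limma compares a list with all other genes at a preset correlation between genes of 0.01. It was repeated with an estimated correlation. Fry in limma tests whether the genes of a list move, on balance, one way. It does not compare them with other genes. Adjustment was over 36 lists. Blood-cell lists written after the values were seen were adjusted among themselves. "Adjusted over the list alone" means Benjamini-Hochberg over the measured members of 1 list.

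Psen2 and Chat were always named. Results for some further genes that these rules pick are not reported here. Otherwise the 10 largest rises and 10 largest falls among passing genes whose groups do not overlap were named for each region's genotype comparison, and 5 and 5 for the other comparisons. Where fewer than 5 passed, the smallest p filled up to 5. Up to 4 members per described list were named by smallest p. Probes without a symbol and names of unnamed transcripts were passed over. The same rule of 10 and 10 was applied to the difference over both regions after its values were seen. 6330418B08Rik, the immunoglobulin lambda constant 3 probe, Apol11b and Ahsp were also named after values were seen.

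Where a gene was not well above background on any array of the lower group, the fold is a bound: "at least" sets the mean of the higher group against the mean of the lower group after each lower value was raised to the dimmest signal the scanner called well above background on that array. Chance separates 10% of genes without overlap when 3 arrays are set against 3.

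The scripts were tested on simulated data, in which every gene varied at random around its mean with its own within-group SD and 200 genes were changed. At 2-fold, 4-fold and 8-fold the basal forebrain comparison recovered 62.7%, 83.6% and 97.0% of them, with 7 unchanged genes passing. Cortex recovered 58.2%, 88.1% and 93.9% with 4, and both regions 68.7%, 91.0% and 98.5% with 11. A list of 15 genes changed 1.5-fold was recovered in each region by camera, with 0 unchanged lists called. Each gene was simulated on its own, with no correlation between the genes of a list. The simulation therefore cannot tell how often camera at the preset correlation calls unchanged lists whose genes vary together. Arrays were also drawn independently, without a slide effect or a tie between the 2 arrays of a mouse. The shares recovered and the counts of unchanged genes passing hold for such data only.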

Results

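Psen2 encodes a catalytic subunit of gamma-secretase, the protease that cuts APP and Notch. The DKO mice lacked Psen2 throughout and carried Cre driven by Chat. The controls (Con) had no Cre and 1 working copy of Psen2. The question is what this genotype does to RNA in basal forebrain, where cholinergic cell bodies lie, and in cortex, which they innervate, with ageing and inflammation in view. Each genotype had 3 mice aged 2 months and labelled male, killed by cervical dislocation, and each mouse gave both regions. All 12 arrays entered: at least 68.9% of probes were well above background on each, and arrays of a group had r of 0.986 to 0.998. All basal forebrain arrays and the cortex arrays of DKO mice 1 and 2 were on slide 1, and the other 4 cortex arrays on slide 2.

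Psen2 RNA was low on all 6 DKO arrays. It stood at -1.86, -1.44 and -1.25 in DKO basal forebrain (mice 1, 2 and 3) against 0.39, 0.25 and 0.42 in Con. In cortex it stood at -1.70, -1.59 and -1.67 in DKO against 0.42, 0.50 and 0.47. Chat, which makes acetylcholine, read -0.08, 0.26 and -0.04 in DKO and 0.33, 1.00 and -0.30 in Con basal forebrain. In cortex Chat read -2.33, -2.35 and -1.66 in DKO and -1.55, -1.34 and -1.95 in Con. Which part of Psen2 is deleted is not given in the sources used here, so its probes show lower RNA and do not place the deletion. A dimmer Psen2 probe was well above background on all 6 Con arrays and on 1 of 6 DKO arrays, so its difference has no exact size.

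**Figure D1:**
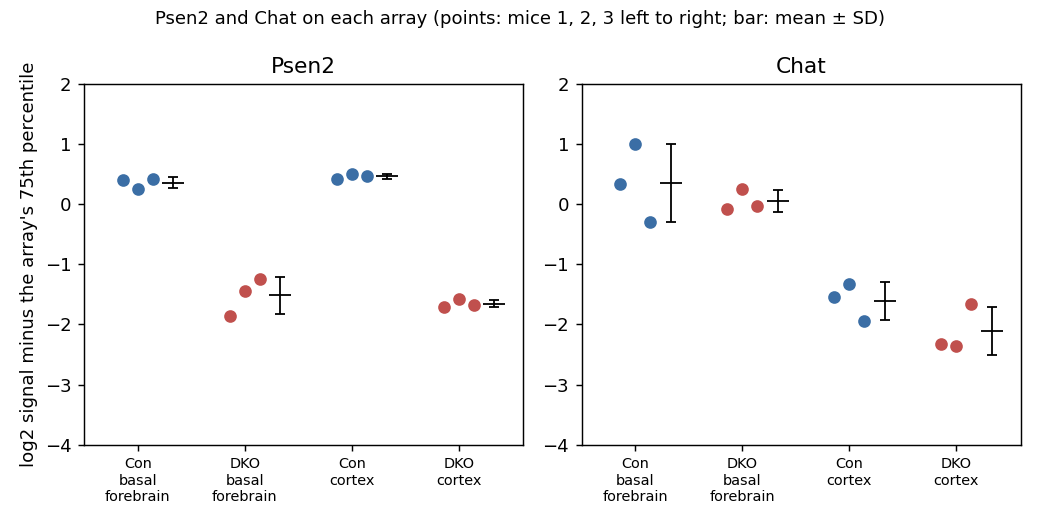
Log2 signal minus the 75th percentile of the array for Psen2 and Chat in 4 groups; points are mice 1 to 3 from left to right (blue Con, red DKO) and black bars the mean and SD. Psen2 lay between -1.86 and -1.25 on the DKO arrays and between 0.25 and 0.50 on the Con arrays.

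Xist, transcribed from the inactive X of females, was well above background in 2 of the mice labelled male. DKO mouse 1 had Xist at -1.89 in basal forebrain and -1.80 in cortex, and DKO mouse 3 at -1.53 and -2.32, while DKO mouse 2 had -8.49 and -8.28 and the Con arrays lay between -9.14 and -6.48. Of 4 Y-linked genes, Ddx3y, Eif2s3y and Uty were not above background on the arrays of DKO mice 1 and 3. The single probe read for Kdm5d stayed well above it there, near control level (-1.20 to 0.04). That probe did not separate these mice from the others, and whether its signal came from Kdm5d was not tested. The mean of the 4, that probe included, was -6.79 to -6.12 on the arrays of DKO mice 1 and 3, -1.15 and -0.80 in DKO mouse 2, and -1.12 to -0.69 in Con. The label and the RNA therefore differ for DKO mice 1 and 3, which were kept. Their Xist, Ddx3y, Eif2s3y and Uty read as in females. Every comparison of DKO with Con thus sets these mice and DKO mouse 2 against Con mice that read as males. Sex as read from RNA is unequal between the genotypes for all genes, and only DKO mouse 2 could part it from genotype. Of the Y-linked and Xist list, 4 members were measured per comparison with a median of -4.61 in basal forebrain and -4.58 in cortex. In each region 3 fell when adjusted over the list alone and 0 by limma over all genes (Eif2s3y, a Y-linked translation factor, -5.96, SE 2.25, adjusted p = 0.971 in basal forebrain).

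**Figure D2:**
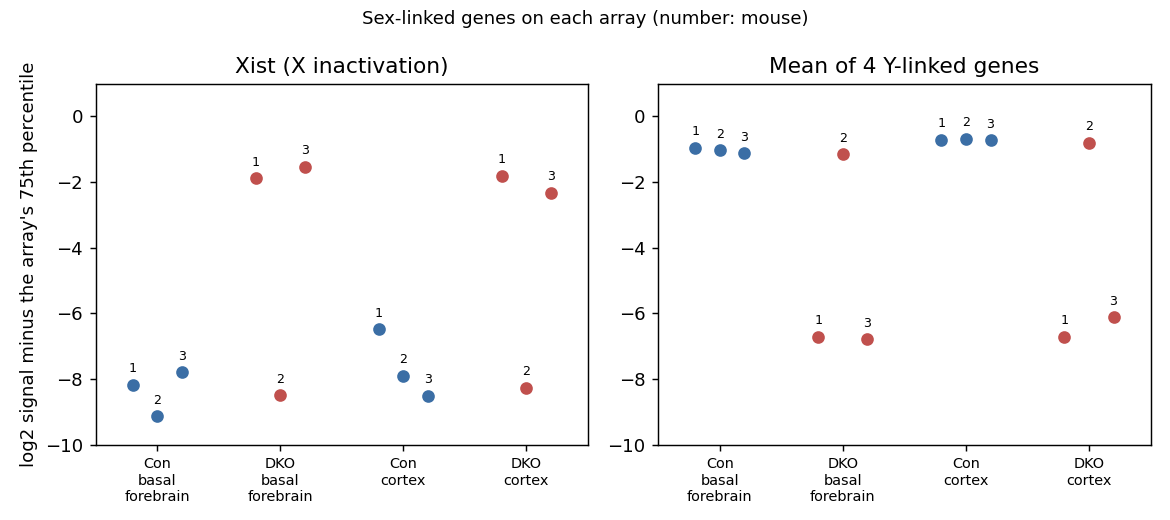
Xist and the mean of 4 Y-linked genes per array, as log2 signal minus the 75th percentile of the array; each point is 1 array, numbered by mouse. DKO mice 1 and 3 had Xist between -2.32 and -1.53 with Y-linked means under -6, although the probe read for Kdm5d among the 4 stayed near control level.

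In basal forebrain 8 genes changed in DKO against Con, 6 up and 2 down, and 5 of the rises with a symbol mark B cells. Ms4a1, a B-cell membrane protein, rose from -8.69 (SD 0.68) to -2.77 (SD 0.26, n = 3 per group), a log2 difference of 5.92 (SE 0.36, at least 16.2-fold, limma adjusted p = 0.0145), on the probe at 19:11325409-11325468. Fcrla, a B-cell Fc receptor-like protein, rose by 4.36 (SE 0.34, at least 4.11-fold, limma adjusted p = 0.0223), and Cxcr5, the receptor that draws B cells to follicles, by 3.56 (SE 0.24, at least 2.40-fold, adjusted p = 0.0145). Spib, a B-lineage transcription factor, rose by 3.46 (SE 0.30, limma adjusted p = 0.0328), Cd79b, a B-cell receptor chain, by 2.49 (SE 0.16, 0.0145), and a probe for immunoglobulin lambda constant 3 by 3.10 (SE 0.24, 0.0223). Psen2 fell by 1.87 (SE 0.16, n = 3 per group, 3.65-fold, limma adjusted p = 0.0328), as the knocked-out gene. Ifi205, an interferon-inducible gene, fell by 2.93 (SE 0.27, at least 1.77-fold lower, limma adjusted p = 0.0377) on the probe at 1:175942245-175942304.

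Chat differed by -0.30 (SE 0.30, limma adjusted p = 0.971) in basal forebrain. The falls of smallest p that did not pass were Inhba, a subunit of activin, at -0.80 (limma adjusted p = 0.145), Rpe65, a retinoid isomerase, at -0.92 (0.511), and Greb1, an oestrogen-responsive gene, at -1.20 (0.517). Granulocyte and red-cell genes had large differences that did not pass, such as S100a9, a neutrophil calcium-binding protein (3.08), and Slc4a1, the anion exchanger of red cells (3.09, SE 0.35, limma adjusted p = 0.0982).

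All 7 erythroid genes were higher in DKO basal forebrain and rose when adjusted over the list alone, with a median of 2.19 (camera up, adjusted p = 6.92e-16, 0.822 with an estimated correlation). Alas2, the first enzyme of red-cell haem synthesis, had 2.61, and the globins Hbb-bt 2.19 and Hba-a2 1.49. The near-identical globin copies are hard for probes to separate, so which copy was read is uncertain. Of 17 peripheral leukocyte genes, 1 rose over all genes and 6 adjusted over the list alone (median 0.16, mean 0.92, camera up, adjusted p = 2.92e-07, 0.822 with an estimated correlation), among them Cd79b, S100a8 (3.14) and S100a9. Interferon response genes were lower: 24 of 29 were negative, with a median of -0.17 and 0 passing (camera down, adjusted p = 0.000404, 0.888 with an estimated correlation). Ifi27 had -0.35, Gbp3 -0.44 and Oas1a -0.40, while Rsad2, an antiviral enzyme, had 1.18.

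Lists that mark vessels, ventricle walls and neighbouring regions were called up in basal forebrain at the preset correlation, each with camera at adjusted p = 0.888 with an estimated correlation. Endothelial genes were among them (median 0.13, 2 of 14 rose adjusted over the list alone, Flt1 0.30 and Vwf 1.09, camera adjusted p = 0.00162), with mural cell (0.20, 0 of 10 passing, 0.0086) and ependymal (0.41, 10 of 10 positive, 1 rose adjusted over the list alone, the ciliary gene Spag16 0.75, 0.0154). So were septum, preoptic area and hypothalamus (0.25, 14 of 17 positive, 0 passing, Nkx2-1 0.40 and Gnrh1 0.32, 0.00162) and thalamus (0.19, 9 of 10 positive, 0 passing, 0.0185). Cholinergic neuron genes were called up too (0.11, 11 of 12 positive, 0 passing, camera adjusted p = 0.0199), with the transcription factor Lhx8 at 0.28 and the neurotrophin receptor Ngfr at 0.23. Glucocorticoid response (0.17, 2 of 14 rose adjusted over the list alone, Lcn2 3.02 and Sult1a1 0.98, camera adjusted p = 0.00414) and reactive astrocyte genes (0.13, 1 of 30 rose adjusted over the list alone, Lcn2, 0.038) were called up. Lcn2 is also a neutrophil granule gene, and without it the reactive astrocyte call ended (camera adjusted p = 0.108) while the glucocorticoid call held (0.0276). Down were homeostatic microglia (-0.01, 13 of 19 negative, 0 passing, Trem2 -0.30 and Aif1 -0.30, camera adjusted p = 0.0228) and gamma-secretase and APP processing (-0.03, 11 of 13 negative, 1 fell, Psen2, 0.0296). The last holds the knocked-out gene, and without Psen2 it was not called (camera adjusted p = 0.243). All 5 of these lists, cholinergic to gamma-secretase, had camera adjusted p = 0.888 with an estimated correlation.

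Basal forebrain showed no call for 23 lists, whose medians lay between -0.15 and 0.10 with camera adjusted p from 0.0542 to 0.895. They were acetylcholine receptors, Notch pathway, disease-associated microglia, astrocyte, cytokines, chemokines and NF-kB, complement, MHC and antigen presentation, senescence and secretory phenotype, p53 and DNA damage response, oxidative phosphorylation, antioxidant response, heat shock and unfolded protein response, lysosome and autophagy, synapse, immediate early genes, circadian clock, excitatory cortical neuron, GABAergic neuron, striatal medium spiny neuron, oligodendrocyte, oligodendrocyte precursor, choroid plexus and meningeal fibroblast. None of their members passed over all genes, and only Aqp4, the astrocyte water channel, fell when adjusted over its list alone (-0.48). Lysosome genes had a median of -0.03 and a mean of 0.01, choroid plexus genes 0.10 and -0.17. With an estimated correlation camera called 0 of 36 lists, and fry, which tests whether the genes of a list move, on balance, one way without comparing them with other genes, called 0 (smallest adjusted p = 0.279).

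Limma tested 25914 genes in basal forebrain. Of these 1146 (4.42%) had an unadjusted p under 0.05, and 2582 (9.96%) separated the groups without overlap where chance gives 10%. Leaving out 1 array gave 0 genes without DKO mouse 3 or Con mouse 3, 1 without Con mouse 1, 13 without DKO mouse 2 and 29 without Con mouse 2. Psen2 passed in the full set (adjusted p = 0.0328) and failed in 9 of 19 alternatives (limma adjusted p 0.00014 to 0.417), with a log2 difference of -1.84 and an adjusted p of 0.226 without Con mouse 3. Spib failed in 10 of 19 (limma adjusted p 0.00101 to 0.417). Ifi205, which is dim, had -0.28 with normexp background correction (limma adjusted p = 0.796, and 0.00171 to 1 over 18 alternatives). Erythroid, leukocyte and interferon calls held without any 1 array. The reactive astrocyte, thalamus, mural and ependymal calls ended without DKO mouse 1 (camera adjusted p 0.0946 to 0.336), and the gamma-secretase, microglia, reactive astrocyte, glucocorticoid and mural calls without DKO mouse 2 (0.111 to 0.529). Gamma-secretase, cholinergic, microglia and ependymal calls ended without DKO mouse 3 (camera adjusted p 0.0941 to 0.475), and the gamma-secretase, cholinergic, microglia and mural calls without Con mouse 3 (0.0503 to 0.578). Without Con mouse 2, 8 calls ended: microglia, reactive astrocyte, glucocorticoid, septum, thalamus, endothelial, mural and ependymal (camera adjusted p 0.0639 to 0.911). Without DKO mice 1 and 3, those with Xist signal, 1 DKO mouse remains and the cholinergic, septum, thalamus and ependymal calls ended (camera adjusted p 0.277 to 0.98).

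In cortex 3 genes changed in DKO against Con. Ms4a1, the B-cell membrane protein, rose by 4.93 (SE 0.44, n = 3 per group, at least 8.88-fold, limma adjusted p = 0.0412). Psen2 fell by 2.12 (SE 0.09, 4.33-fold, limma adjusted p = 0.000326). The unnamed transcript 6330418B08Rik, of unknown function, fell by 2.14 (SE 0.18, limma adjusted p = 0.0412) and had -2.08 in basal forebrain. Chat differed by -0.50 (SE 0.23, limma adjusted p = 0.275). Other Chat probes well above background on all 12 arrays differed by 0.01 and -0.40 in cortex, and by 0.09 and -0.09 in basal forebrain.

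Next by p in cortex, and not passing, were Apol11b, an apolipoprotein L (2.44, limma adjusted p = 0.0535), Cd79b (2.47, SE 0.24, 0.0535), Bcl3, a regulator of NF-kB (1.54, 0.0785), and Plac8, a leukocyte gene (2.27, 0.0838). Falls that did not pass were Dusp23, a phosphatase (-0.59, limma adjusted p = 0.176), Srrm4os, an antisense transcript (-1.11, 0.184), Zfp658, a zinc-finger gene (-0.30, 0.203), and Tnnc1, a troponin (-0.94, 0.224).

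Erythroid and leukocyte genes were higher in DKO cortex too. All 7 erythroid genes rose when adjusted over the list alone, median 1.69 (camera up, adjusted p = 1.28e-10, 0.773 with an estimated correlation), with Hbb-bt at 2.01, Hbb-b2 at 1.69 and Hba-a1 and Hba-a2 at 1.23 each, copies that the probes may not separate. Of 15 leukocyte genes 6 rose adjusted over the list alone (median 0.61, mean 1.16, camera up, adjusted p = 2.87e-06, 0.773 with an estimated correlation), among them S100a8 (3.85), S100a9 (3.64) and the neutrophil granule gene Ngp (3.08). Choroid plexus genes were all higher, 14 of 14, median 0.43 (camera up, adjusted p = 1.33e-05, 0.818 with an estimated correlation). Slc4a5, a bicarbonate transporter, had 1.00 and Col8a1, a collagen, 0.80, the 2 that rose adjusted over the list alone.

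Cholinergic neuron genes were lower in DKO cortex: 11 of 12 were negative, median -0.54, and 2 fell adjusted over the list alone, the protease Ecel1 at -0.59 and Ngfr at -0.85 (camera down, adjusted p = 0.0356, 0.856 with an estimated correlation). The acetylcholine and choline transporters Slc18a3 and Slc5a7 had -0.75 and -0.62. Most of this lay in DKO mice 1 and 2, whose arrays were on the other slide: Slc18a3 read -3.06, -2.46 and -1.96 in DKO mice 1 to 3 against -1.88 to -1.64 in Con, and Slc5a7 -2.93, -2.16 and -1.80 against -1.84 to -1.57. Homeostatic microglia genes were lower (17 of 19 negative, median -0.16, 0 passing, Aif1 -0.36 and Trem2 -0.32, camera down, adjusted p = 0.0356, 0.856 with an estimated correlation). Called up were glucocorticoid response (median 0.43, 2 of 14 rose adjusted over the list alone, Lcn2 3.28 and Sult1a1 1.48, camera adjusted p = 1.99e-05) and MHC and antigen presentation (0.14, 15 of 20 positive, 0 passing, Cd74 0.76, H2-D1 0.37, 0.00645). So were senescence and secretory phenotype (0.11, 4 of 21 rose adjusted over the list alone, Igfbp7 0.43, Igfbp3 0.36, Timp2 0.37 and Cxcl1 1.97, 0.00778) and complement (0.14, 1 of 16 rose adjusted over the list alone, Cfb 1.69, 0.0356). These 4 had camera adjusted p from 0.773 to 0.818 with an estimated correlation.

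No call was made for 27 lists in cortex, with camera adjusted p from 0.055 upward. Of oligodendrocyte genes 14 of 15 were negative (median -0.27, camera adjusted p = 0.055), and Mobp, a myelin gene, rose adjusted over the list alone (0.51). Interferon response had a median of 0.00 (camera adjusted p = 0.714), the synapse list 0.01 (0.0912), ependymal -0.24 (0.352) and gamma-secretase -0.16 (0.553). Fry called the last down (adjusted p = 0.0094), with 8 of 13 negative, and not without Psen2 (0.647). Single members passed adjusted over the list alone in the antioxidant (Mt1, a metallothionein, 0.36), cytokine (Cxcl1), meningeal (Col3a1, a collagen, -0.96) and excitatory neuron (Nrn1 -0.48) lists, 2 in reactive astrocyte (Lcn2, and the cytokine receptor Osmr 0.78), 2 in endothelial (Vwf 1.75, Ly6c1 0.63) and 4 in astrocyte (Fgfr3 0.31, Slc1a2 0.20, Gjb6 0.48, Aqp4 -0.72). Medians and means differed in sign for the astrocyte, cytokine, interferon, oxidative phosphorylation, lysosome, immediate early, septum, endothelial and meningeal lists, and camera pointed up with a negative median and mean for acetylcholine receptors, p53, antioxidant, striatal, thalamus and mural cell.

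Limma tested 25631 genes in cortex. Of these 4835 (18.9%) had an unadjusted p under 0.05, 3081 of them lower, and 5733 (22.4%) separated the groups where chance gives 10%. Slide 1 holds no Con cortex array, so with slide as a block (4 genes passed), as among the 4 arrays of slide 2, DKO mouse 3 stands alone against the 3 Con mice. On slide 2 alone the spread among DKO mice is unmeasured, so only the sizes of differences are read there. Psen2 then had -2.13 (limma adjusted p = 0.00251 with the block, 2.91e-07 to 0.0759 over 21 alternatives). Ms4a1 had 5.02 (limma adjusted p = 0.118 with the block, 7.29e-05 to 0.402 over 20 alternatives, failing in 10), and Cd79b 2.86. Leaving out DKO mouse 3 gave 9724 genes, DKO mouse 2 gave 8, Con mouse 1 gave 2, and Con mouse 2 or 3 gave 1.

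With slide as a block, which again reads DKO mouse 3 alone against Con, 10 lists were called in cortex, 4 of them shared. The calls for erythroid, leukocyte, senescence and choroid plexus genes held, while cholinergic, microglia, complement, MHC and glucocorticoid calls ended (camera adjusted p 0.224 to 0.542). Slc18a3 then had -0.22 and Chat -0.05, and oligodendrocyte genes were called up (camera adjusted p = 0.0209). The cholinergic call also ended without DKO mouse 1 (camera adjusted p = 0.103) or 3 (0.0879), and senescence without DKO mouse 3 (0.0507). Microglia, complement and MHC calls ended without DKO mouse 2 (camera adjusted p 0.057 to 0.148), complement without Con mouse 2 (0.107) and microglia without Con mouse 3 (0.109). With DKO mouse 2 alone against Con the cholinergic and choroid plexus calls ended (camera adjusted p = 0.249 and 0.247). Camera with an estimated correlation called 0 of 36 lists in cortex, against 9 at the preset correlation.

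**Figure D3:**
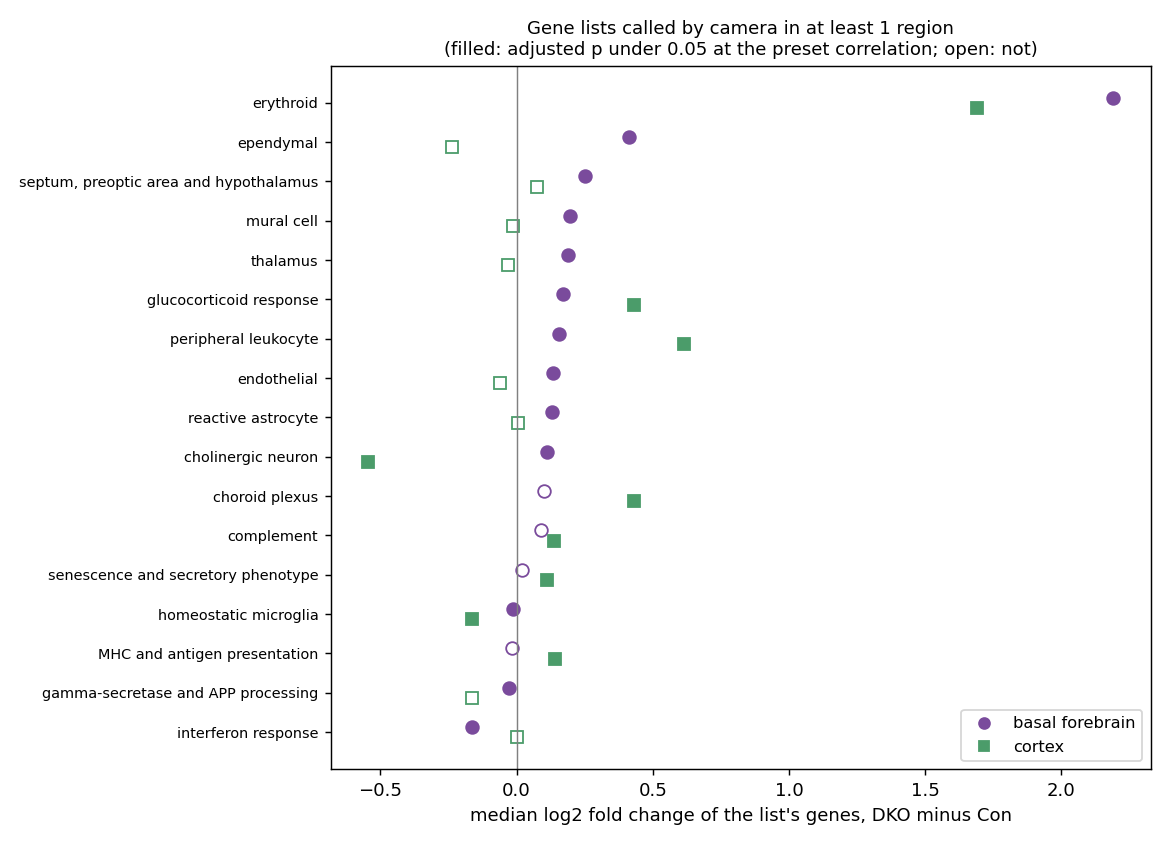
Median log2 difference (DKO minus Con) of the 17 lists called in at least 1 region; purple circles are basal forebrain, green squares cortex, filled where camera at the preset correlation gave an adjusted p under 0.05. Erythroid genes stood at 2.19 and 1.69, and cholinergic neuron genes at 0.11 and -0.54.

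Averaged over both regions of each mouse, 42 genes changed in DKO, 38 up and 4 down, and 25 of the rises were genes of blood cells by lists written after the values were seen. Named by log2 difference, whose order is not set where Con was not above background, were Ms4a1 (5.43, SE 0.37, n = 3 mice per genotype, at least 12-fold, limma adjusted p = 0.00189), the secreted granulocyte protein Wfdc21 (4.08, SE 0.49, 0.0227), the basophil protease Mcpt8 (3.85, at least 3.78-fold, 0.00792), Fcrla (3.81, at least 2.82-fold, 0.0056) and S100a8 (3.50, SE 0.32, 0.00805). Also named were Ltf, lactoferrin of neutrophils (3.45, limma adjusted p = 0.00805), S100a9 (3.36, 0.00864), Cxcr5 (3.22, at least 1.90-fold, 0.00864), Retnlg, a neutrophil resistin-like protein (3.08, 0.0491), and Spib (3.08, 0.0106). Red-cell genes rose as well: Slc4a1 by 2.38 (SE 0.14, limma adjusted p = 0.000968), Alas2 by 2.39 (0.0202) and Ahsp, the haemoglobin chaperone, by 2.75 (0.00265). Psen2 fell by 1.99 (SE 0.10, limma adjusted p = 0.000662), Ifi205 by 2.45 (at least 1.23-fold lower, 0.0147), 6330418B08Rik by 2.11 (0.0289) and Inhba by 0.55 (0.0491).

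All 7 erythroid genes rose over all genes in both regions together (median 2.10, camera up, adjusted p = 5.15e-20, 0.339 with an estimated correlation, fry adjusted p = 0.0289), and 5 of 17 leukocyte genes did (7 adjusted over the list alone, median 0.40, mean 1.03, camera 5.29e-09, 0.339 with an estimated correlation). Rsad2 was the only interferon gene to rise (0.97, SE 0.12, limma adjusted p = 0.0234), with no call for its list (camera adjusted p = 0.264). Camera called 9 further lists, each at 0.799 with an estimated correlation. Up were glucocorticoid response (adjusted p = 3.82e-05), choroid plexus (0.0135), reactive astrocyte (0.014), septum (0.014), complement (0.0222) and senescence (0.0291). Down were oligodendrocyte (0.0101), homeostatic microglia (0.0135) and gamma-secretase (0.0479, and 0.305 without Psen2). Without Lcn2 reactive astrocyte had 0.0471 and glucocorticoid response 0.000804 (camera adjusted p). In the microglia list Trem2 (-0.31) and Aif1 (-0.33) fell adjusted over the list alone, and in the oligodendrocyte list Mbp (-0.50) and Ugt8a (-0.68), genes of myelin.

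Of the 38 rises 12 belong to the erythroid or leukocyte lists. Across 24777 genes the differences of the 2 regions had r = 0.27, and 2 genes passed in both. The same mice gave both regions, and deviations from the group mean in the 2 regions of a Con mouse had r of 0.204 to 0.317. In DKO mice that r was -0.0455 to 0.183, and 1 of 3 basal forebrain arrays matched best the cortex array of its own mouse. The r of 0.27 is not independent support for a genotype difference. Limma tested 26768 genes. Of these 2891 (10.8%) had an unadjusted p under 0.05, 1188 higher and 1703 lower, the opposite balance to the genes that passed, and 4479 (16.7%) separated the mice where chance gives 10%. With slide as a block, where the genotype difference rests on DKO mouse 3 alone, 0 genes passed (limma, 867 at an unadjusted p under 0.05, Psen2 adjusted p = 0.0689, and 9.68e-07 to 0.0689 over its 19 alternatives), and with mouse as a random block over the 12 arrays 65 passed, 37 of them shared. Leaving out 1 mouse gave 20 genes without DKO mouse 2, 178 without DKO mouse 3, 22 without Con mouse 1 or 3, and 71 without Con mouse 2. Of 19 alternatives Inhba failed in 14 (limma adjusted p 0.00657 to 0.425), Rsad2 in 12 (0.0111 to 0.425) and Retnlg in 12 (0.0069 to 0.898).

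**Figure D4:**
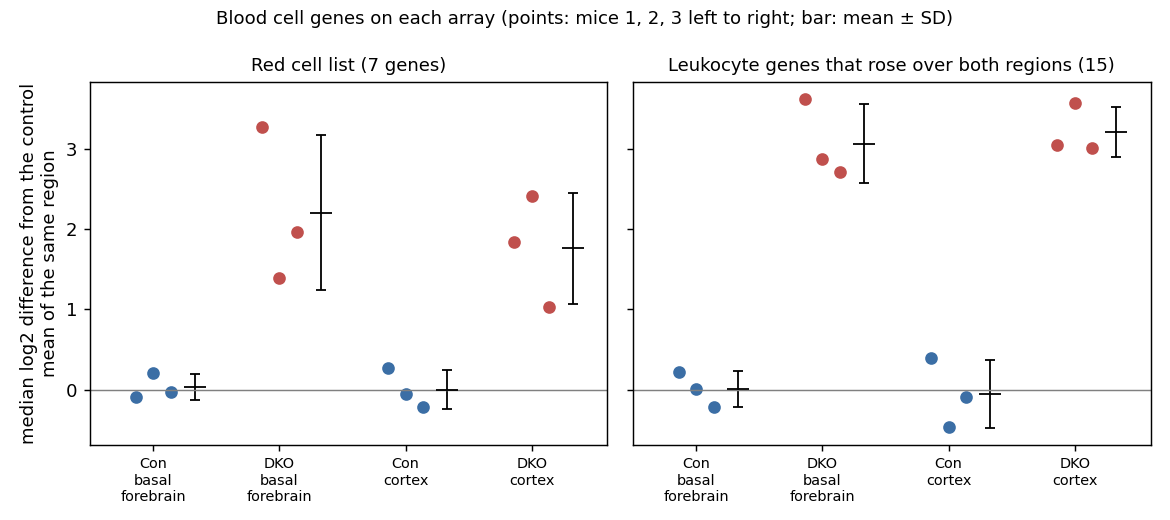
Median log2 difference from the Con mean of the same region for 7 erythroid genes and for 15 leukocyte genes that rose over both regions; points are arrays, bars the mean and SD per group. Leukocyte medians were 2.71 to 3.62 on the DKO arrays and -0.46 to 0.39 on the Con arrays.

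No gene passed for a genotype difference that differed between the regions. On simulated data this comparison recovered 50.75% of genes changed 2-fold, so differences of that size can be missed. Limma passed 0 of 26768 genes (smallest adjusted p = 0.56), 2247 (8.39%) had an unadjusted p under 0.05, and 3799 (14.2%) separated the mice where chance gives 10%. Psen2 had 0.25 (SE 0.19, limma adjusted p = 0.626) and Chat 0.21 (SE 0.41, 0.853). Smallest in p, each at a limma adjusted p of 0.56, were the neurotrophin receptor Ngfr (1.07), the pseudogene Cyp4b1-ps2 (3.33), the lymphoid surface gene Ly6d (2.34), Hjv, an iron regulator (1.57), and Cby2 (1.52). In the other direction they were Psrc1, a spindle gene (-1.21), the retinal transporter Abca4 (-0.69), Wnt10a, a signalling ligand (-1.0), Rbbp6, a ubiquitin ligase (-0.53), and Wdr86 (-1.40). Leaving out DKO mouse 3 gave 1579 genes, and leaving out Con mouse 2 gave 7. Mouse as a block gave 0 and slide as a block 0. Camera called 5 of 36 lists at the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.914) and fry 0 (0.959).

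Basal forebrain and cortex of Con mice differed in genes of neuron kinds and of the choroid plexus. Oxt, the hormone oxytocin, was higher in basal forebrain by 5.24 (SE 0.91, n = 3 per region, limma adjusted p = 0.000816). So were Hmx3 (5.17, 7.11e-05) and Lhx5 (4.91, 6.19e-05), transcription factors of the hypothalamus, Cckar, a cholecystokinin receptor (4.78, at least 19.0-fold, 1.32e-06), and Gnrh1, the hormone that releases gonadotropins (4.77, SE 0.13, 1.15e-09). Lower in basal forebrain were choroid plexus genes: Ttr, which carries thyroid hormone (-8.01, SE 0.93, limma adjusted p = 4.49e-05, -1.94, SD 2.74, against 6.07, SD 0.47), Slc4a5 (-5.63, at least 31.3-fold, 2.81e-07), Kcne2, a potassium channel subunit (-5.61), Prr32 (-5.50, at least 13.4-fold) and Folr1, a folate receptor (-5.39). Chat was higher in basal forebrain by 1.95 (SE 0.29, limma adjusted p = 0.000267), and Psen2 had -0.11 (0.511).

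All 12 cholinergic neuron genes were higher in Con basal forebrain (median 3.10, camera adjusted p = 6.63e-13, 0.175 with an estimated correlation, fry adjusted p = 1.19e-06), as were all 14 striatal genes (1.77, camera 7.52e-12) and 11 of 17 septum, preoptic and hypothalamus genes (1.70, 5.69e-08). Excitatory cortical neuron genes (10 of 14 lower, 1 higher, median -2.31, camera adjusted p = 0.000415) and choroid plexus genes (10 of 14 lower, 2 higher, -1.55, 0.00128) were lower, as were synapse genes (17 of 26 lower, 0.00063). Interferon response (16 of 29 higher, 2 lower, median 0.44, camera adjusted p = 1.39e-05), MHC (12 of 20 higher, 5.86e-05) and meningeal genes (10 of 13 higher, median 0.91, 0.000331) were higher. Camera called 16 of 36 lists, 0 with an estimated correlation, and fry called 21. In limma 12986 of 26768 genes passed, 4916 higher and 8070 lower, and 16390 (61.2%) separated the regions where chance gives 10%. The Con regions lay on different slides, and with slide as a block, estimated only from DKO cortex mice 1 and 2 against 3, 2850 passed, 2555 of them shared. With mouse as a block 13101 passed. Leaving out Con mouse 1 gave 6816 and Con mouse 2 gave 8235.

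Regional differences in DKO mice followed those in Con across genes (r = 0.854), with 5 lists unequal between the genotypes by camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.914) or by fry (0.959). Higher in DKO basal forebrain were Oxt (7.06, n = 3 per region, limma adjusted p = 9.86e-05), Hmx3 (6.43, at least 37.7-fold), Hmx2 (5.95, at least 12.5-fold) and Gbx2 (5.73, at least 25.8-fold), which pattern the hypothalamus and thalamus, and Lhx8 (5.57, 2.55e-07). Lower were Ttr (-9.65, SE 0.93, limma adjusted p = 1.01e-05), Slc4a5 (-6.93, at least 54.8-fold), Prr32 (-6.34, at least 16.6-fold) and Kcne2 (-6.29). Chat was higher by 2.16 (limma adjusted p = 0.000131). All 12 cholinergic genes were higher (median 3.84, camera adjusted p = 1.4e-14, 0.117 with an estimated correlation), with 14 of 14 striatal genes (1.86) and 12 of 17 septum genes (2.09), while 11 of 14 excitatory neuron genes (-2.30) and 12 of 14 choroid plexus genes (-1.86) were lower. Camera called 15 of 36 lists, 0 with an estimated correlation, and fry called 21.

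In limma 10231 genes passed between the regions of DKO mice, 4914 higher and 5317 lower (2489 and 1223 at 2-fold or more, 5636 and 4340 with the mean of probes, 5568 and 5168 with cyclic loess, so the balance turns), with 13005 (48.6%) apart where chance gives 10%. Of these and the Con genes, 3372 were higher and 4338 lower in both genotypes, where independent lists would share 902.5 and 1603, and 1 was opposite. The differences had r = 0.854 across 26768 genes, which is a count of genes and not of replicates. With mouse as a block 10319 passed and with slide as a block 9734. Without DKO mouse 2 there were 6318.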

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

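The tests for blood, sex, slides, mouse and dissection below were chosen after the results were seen; the tests of flanking DNA, probe variants, probe GC content and exchanged labels were chosen before.

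Changed genes gathered near Psen2. Of the 8 genes that passed in either region apart from the edited genes, 3 lay within 10 Mb of an edited gene or Chat, all of them near Psen2: 6330418B08Rik (5.17 Mb), Ifi205 (6.22 Mb) and Fcrla (9.31 Mb), against 2.48% of 26619 genes (1-sided Fisher exact p = 0.000771, odds ratio 23.7, 3.68 to 122). Without Fcrla, a B-cell gene that rose, 2 of 7 remained (Fisher exact p = 0.0118), and 0 of 8 lay within 5 Mb and 3 of 8 within 20 Mb (Fisher exact p = 0.0046). These values are consistent with DNA of another strain carried along with the Psen2 allele, and 20.9% of the 249 genes there had a p under 0.05 against 10.8% of all genes. Variants under single probes cannot be told apart from changed RNA, since 0 other probes of the fallen genes were usable.

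Leukocyte genes rose in all 6 DKO arrays, and so did erythroid genes: the erythroid median was above every Con array on 6 of 6, from 1.04 to 3.27. That fits more blood left in the DKO tissue, a candidate explanation that would raise white and red cells together. Set against it, T and NK cell genes moved little (median 0.19 over both regions, 0 of 14 passing, camera adjusted p = 0.0143 and 0.335 with an estimated correlation). So did platelet genes (0.08, 1 of 9 passing, camera 0.0225 and 0.252), while monocyte genes were higher (0.30, 9 of 10 positive, 1 passing, camera 4.81e-06 and 0.141). These camera p-values were adjusted over the blood-cell lists alone, which were written after the values were seen. B-cell medians did not follow the erythroid ones: 1.585, 2.11 and 2.28 in DKO basal forebrain (mice 1 to 3) against 3.27, 1.39 and 1.96. In DKO cortex they were 0.82, 0.97 and 1.71 against 1.84, 2.41 and 1.04. Granulocyte medians were 1.37, 1.345 and 0.80 in DKO basal forebrain (mice 1 to 3) and 0.64, 1.13 and 0.82 in DKO cortex. In each region they were highest on the same array as the erythroid medians, but the remaining mice came in the opposite order. The labels name no perfusion, and whether DKO blood itself differed was not tested. Slides are excluded as the whole source, since all basal forebrain arrays shared a slide and Cd79b rose there by 2.49 (SE 0.16); the median of 15 leukocyte genes was 3.08 there, a value favoured because they were chosen for rising over both regions. Unequal sex remains open: the 1 DKO mouse without Xist signal had medians of 2.87 and 3.57, and 1 mouse cannot tell.

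The cortex arrays of DKO mice 1 and 2 stood apart from that of mouse 3, with an SD of the difference across genes of 0.56 against 0.32 in basal forebrain and 0.30 in Con cortex. A difference between the mice that both regions share is excluded as the whole source, because the same difference in basal forebrain had r = -0.0455 with it; a difference confined to cortex was not tested. A slide effect tied to probe GC content (absolute r 0.133 in cortex and 0.119 in basal forebrain) and unequal dissection (r = 0.486 with the region difference of Con) cannot be told apart, since the Con regions lay on different slides. Con cortex arrays that share a slide gave r = -0.171 with GC content, which counts against a slide source of it.

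For 5 lists the genotype difference had opposite or unequal medians in the 2 regions, called by camera at the preset correlation (each with adjusted p = 0.914 with an estimated correlation and 0.959 by fry). The medians of basal forebrain minus cortex were 0.58 for cholinergic neuron (0.11 and -0.54, camera adjusted p = 0.0033), -0.49 for choroid plexus (0.10 and 0.43, 0.000568), -0.28 for excitatory cortical neuron (-0.15 and 0.04, 0.0464), -0.16 for MHC and antigen presentation (-0.02 and 0.14, 0.00542) and -0.11 for interferon response (-0.17 and 0.00, 0.00542). The cholinergic and choroid plexus differences might come from unequal cutting of the tissue, which was left open (r = 0.486, shared with slide). In cortex the medians of DKO mice 1 and 2 minus mouse 3 were -0.65 for cholinergic, -0.13 for striatal, 0.11 for septum, 0.06 for thalamus, -0.30 for choroid plexus and 0.15 for excitatory neuron genes. Cholinergic, striatal and excitatory genes thus lay further from basal forebrain in mice 1 and 2, while septum, thalamus and choroid plexus genes and the positive r lay nearer to it, so the values point different ways.

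When the arrays were exchanged between groups there were 10 splits of 3 against 3, too few for a share under 0.05. In basal forebrain 2 splits gave at least the 8 genes of the real one; the highest other, DKO mice 2 and 3 with Con mouse 2, gave 1214, which points to a structure of the samples. In cortex 1 split, the real one, gave 3 and the highest other 0, and over both regions 1 gave 42 and the highest other 1. For the difference between regions all 10 gave 0. Between regions, 1 split gave 12986 in Con with the highest other 0, and 1 gave 10231 in DKO with the highest other 1; the splits that part as many mice gave 0.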

How the results depend on the processing

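The alternatives without DKO mice 1 and 3, with slide 2 only, and with other windows, and the list tests with slide as a block or without 1 member, were chosen after the data were seen. Signal over background limits the dim genes: both filters moved the counts between genotypes and left those between regions within 1.5-fold. In basal forebrain 8 genes passed, against 5 with normexp, 3 without a filter, 2 with the strict filter, 62 with array weights, 26 with all 12 arrays in 1 fit, 0 with the number shared across genotypes as a block, 0 without DKO mice 1 and 3, and 0 to 29 leaving out 1 array. In cortex 3 passed, against 2 with cyclic loess, 1 without a filter, 2 with the strict filter, 0 with the mean of probes, 1 with trend=FALSE, 15373 with array weights, 25 with all 12 arrays, 2 with the shared number as a block, 7733 without DKO mice 1 and 3, 27 on slide 2 only, and 1 to 9724 leaving out 1 array. Up and down were 1 and 2 in cortex, 3 and 1 with quantile or the authors' values, 1 and 1 with cyclic loess. Over both regions 42 passed, against 16 without a filter, 22 with the strict filter, 14 with trend=FALSE, 993 (462 up and 531 down) with array weights, 0 with slide as a block, 65 with mouse as a random block, 8 without DKO mice 1 and 3, and 20 to 178 leaving out 1 mouse. The interaction had 0, against 10603 with array weights, 15 without DKO mice 1 and 3, and 0 to 1579 leaving out 1 mouse. Between regions Con had 12986, against 4303 at 2-fold or more, 20356 with array weights, 2850 with slide as a block, 6816 to 13866 leaving out 1. DKO had 10231, against 3712 at 2-fold or more, 15991 with array weights, 3534 without DKO mice 1 and 3, 6318 to 10630 leaving out 1. Camera called 13 lists in basal forebrain, 0 with an estimated correlation, 0 by fry, 9 to 17 leaving out 1 array. In cortex it called 9, then 0, 1 and 8 to 10. Genes near the loci were 3, 0 at 5 Mb and 3 at 20 Mb. Eif2s3y reversed in cortex to 0.40 without DKO mice 1 and 3 (limma adjusted p = 0.036), where 1 DKO mouse is left and only Con gives the spread. Among genes at an unadjusted p under 0.05 in basal forebrain 60.0% were higher, 74.6% with normexp and 47.9% with quantile scaling. In the interaction the shares were 67.8%, 76.7% and 48.4%. Of 2900 settings of 153 named genes in basal forebrain 2778 stayed the same, 52 were weaker and 23 stronger. In cortex it was 2762 of 3206, 11 and 389. Other counts stayed within 1.5-fold. The cause of these shifts was not tested.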

Other observations

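Lists of single blood-cell kinds were written after the values were seen, with some members taken from changed genes, so their tests describe and do not test anew.

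B-cell genes rose over both regions: 7 of 16 passed, with a median of 1.67 (camera with an estimated correlation, adjusted p = 0.0384). Red-cell and precursor genes rose too (9 of 12, median 2.02, 0.0264), and so did granulocyte genes (7 of 21, 1.02, 0.0264). With an estimated correlation none of these 3 lists was called in cortex (camera adjusted p = 0.112, 0.1 and 0.1 for B-cell, red-cell and granulocyte genes). T and NK cell genes had a median of 0.19 with 0 of 14 passing, monocyte genes 0.30 with 1 of 10 and platelet genes 0.08 with 1 of 9. Cd3e, a T-cell receptor subunit well above background on all 12 arrays, had -0.17 over both regions (SE 0.13, limma adjusted p = 0.605).

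The 15 leukocyte genes, chosen because they rose, had medians per array of 3.62, 2.87 and 2.71 in DKO basal forebrain and 3.05, 3.57 and 3.01 in DKO cortex. The erythroid medians were 3.27, 1.39 and 1.96, and 1.84, 2.41 and 1.04.

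Ttr, the abundant choroid plexus transcript, ranged from -4.92 to 0.47 among the Con basal forebrain arrays and from -3.23 to -2.92 among the DKO ones, against 5.60 to 6.74 in cortex. So the cortex pieces carried choroid plexus RNA in every mouse, and its amount may follow the cut; the test against the region difference of Con gave r = 0.486, which a slide difference would share.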
